A study of Mus musculus with 3 samples.

How the data were processed

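Chromatin from bone marrow-derived macrophages of WT and GRdim mice was immunoprecipitated with an antibody against GR and sequenced, with 1 library for each genotype; an input library is also described, and no values of it are analysed here. Per the submitters' processing notes, reads were aligned with Bowtie to the mouse genome build mm9; the Bowtie version and options, the peak caller, its thresholds and how the input was used are not given in the sources used here. Each list covers 1 library, and the labels mention no pooling.

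The deposited files list a position, a height and a strand sign for each peak. The heights are taken as RPM (reads per 1000000 reads) as the authors computed them: the peak names carry the mark 1rpm, no listed height is below 1, and no header states the unit. A height is a value of the peak in its own library, and the files do not tell whether input signal was subtracted. The floor of 1 RPM removes every weaker site, so a site absent from a list may still be bound below the floor, or may have failed a filter that is not described; absence from a list is therefore written as "not listed". The start and end positions (0-based in the deposited files, printed 1-based here) showed a width of 200 bp for all peaks, so the lists carry no information on the breadth of binding.

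The value of 1 read was fitted as the step, within a preset range, whose whole multiples lie closest to all heights of a list. Steps outside that range were not tried, and a step as small as the rounding of the heights would also give whole numbers. Within a tolerance of 0.1 read, 1075 of 1076 WT heights and 822 of 822 GRdim heights were whole numbers of reads. The step was 0.0676 RPM in WT and 0.0659 RPM in GRdim, which implies about 14800000 and 15200000 reads if the unit is RPM. The listed peaks then hold 23827 and 18152 reads, 0.161% and 0.120% of each library. No file states read numbers, so every read number and the test of reads at shared sites rest on this fit; a fit that takes the lowest listed height as 1 read does not give whole numbers, since the floor lies at 15 or 16 reads. On this fit depth was nearly equal, and a peak at the floor rests on 15 or 16 reads. Reads carry no molecular identifiers, so intervals cover counting error only.

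Peaks were called shared if they overlapped by at least 1 base, which for these widths means midpoints less than 200 bp apart. Shares carry 95% exact binomial (Clopper-Pearson) intervals over peaks. Random placement moved each GRdim peak within the span of its chromosome covered by both lists, 1000 times with a fixed seed, and a one-sided permutation p was taken. Heights of shared and other peaks were compared by the difference of medians with 100000 permutations, two-sided, and the agreement of heights by Spearman's rho with the same number of permutations. Reads at each shared site were compared with an exact binomial test against the ratio of the implied depths, and numbers of peaks between lists with Fisher's exact test. The tests over shared sites, over chromosomes and over the 3 heights of tall peaks were each adjusted by the Benjamini-Hochberg method; the separate test of chromosome X without Y peaks was not adjusted. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. On simulated lists, 300 planted common sites among 822 peaks gave 300.25 overlaps on average in 20 runs. The step fit returned the right number of reads for 100% of simulated peaks. Planted sites were placed so as to overlap, and simulated depths lay inside the range of steps searched. These runs therefore check the code and not its assumptions.

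The design, the alternatives and the rule for naming peaks were fixed before the data were examined. The rule named the 5 tallest shared, WT-only and GRdim-only peaks and the 3 windows of 100 kb with the most peaks in each list, ties ordered by summed height. The ranking of shared peaks by summed height, the naming of autosomal peaks, the test of reads at shared sites, the median ratio at shared sites of 4 RPM or more in sum (with 2000 bootstrap draws), the comparisons by chromosome and by height bin, the comparison of tall peaks, the analysis of neighbouring peaks and all results without chromosome Y were added after the data had been seen. Alternatives covered the overlap that counts as shared (50% reciprocal, midpoints within 100 bp, edges within 500 bp), stricter heights, lists of equal length, merged neighbouring peaks and narrower random placement.

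A total of 4 planned comparisons were not run: distance to gene starts, annotation of peaks, sequence motifs (GR sites among them) and fixed gene lists. All of them need a genome or annotation of mm9, and the gene table at hand is of GRCm38. The lists extend on chromosome 1 to 196821671, beyond the last gene of that table at 195291439, so the builds were not mixed and no peak is tied to a gene here.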

Results

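Binding of the glucocorticoid receptor (GR), the steroid-activated transcription factor encoded by Nr3c1, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in macrophages grown from mouse bone marrow. Cells came from wild-type mice (WT) and from GRdim mice, which carry a point mutation in the dimerization loop of the receptor's DNA-binding domain. The comparison asked where the receptor sat on the genome with and without that mutation. There was 1 ChIP library for each genotype and 1 input library, and a peak list was analysed for each ChIP library. The protocol names dexamethasone, a synthetic glucocorticoid, at 1 µM and the bacterial endotoxin LPS at 100 ng/ml for 3 hours, given alone or together; the labels do not say which combination these ChIP libraries received. With 1 library for each genotype, the spread between animals is unknown, and every p-value below compares these libraries or peak lists and not the genotypes.

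The WT list held 1076 GR peaks and the GRdim list 822, each peak 200 bp wide. Peak heights, which are the authors' own values in RPM (reads at the peak per 1000000 reads of its library), had a median of 1.22 (quartiles 1.08 and 1.55) in the WT list and of 1.25 (quartiles 1.12 and 1.58) in the GRdim list. The tallest peak reached 15.48 RPM in WT, on chromosome Y, and 7.97 RPM in GRdim. Outside chromosome Y, where no GRdim peak was listed, the tallest WT peak reached 7.91 RPM. Both lists stop at a floor of 1 RPM, and the lowest listed heights were 1.01 and 1.05 RPM. The heights rise in even steps, which were taken as whole reads. On that reading the lowest peaks held 15 reads in WT and 16 in GRdim, and the medians were 18 and 19 reads. The implied library depths were about 14800000 reads in WT and 15200000 in GRdim. A peak at the median therefore rests on fewer than 20 reads, so single low peaks are imprecise, and the intervals below cover counting error only.

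The first comparison was which sites the receptor occupied in both genotypes. A WT and a GRdim peak overlapped by at least 1 base at 242 sites, which is 22.5% of WT peaks (95% exact binomial interval 20.03 to 25.1) and 29.4% of GRdim peaks (26.3 to 32.7). There were 834 peaks in the WT list alone and 580 in the GRdim list alone, out of 1656 distinct sites. Shared peaks lay close on top of each other: the midpoints were 23.5 bp apart in the median, and 189 of the 242 pairs (78.1%) lay within 50 bp. The tallest shared site was on chromosome 5, at 114395281 to 114395480 (mm9; WT coordinates), with 4.87 RPM in WT and 7.97 RPM in GRdim, where it was the tallest peak of the list. The next sites by summed height were on chromosome 3 at 146320445 to 146320644 (7.91 RPM in WT and 4.28 in GRdim) and on chromosome 2 at 152631907 to 152632106 (4.87 and 4.42). They were followed by chromosome 3 at 9886751 to 9886950 (3.99 and 5.07) and chromosome 1 at 84299425 to 84299624 (3.58 and 4.35). When the GRdim peaks were placed at random on their own chromosomes, 0.138 of them overlapped a WT peak on average and at most 2 did in 1000 placements, against 242 observed (one-sided permutation p = 0.001, the smallest these placements can give). Placement within 5 kb of each original position gave 11.4 ± 3.2 overlaps (SD over 1000 placements), and the observed number was 21.3 times as high (permutation p = 0.001). A shared peak moved this little can fall back onto its own WT peak. The size of this fold therefore depends on how far a peak may move.

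Heights were then compared between shared sites and sites listed in 1 library. In the WT list the median height was 1.42 RPM for the 242 shared peaks (quartiles 1.22 and 1.89) and 1.15 RPM for the 834 WT-only peaks (quartiles 1.01 and 1.42). The GRdim list gave 1.52 RPM (quartiles 1.25 and 1.98) for shared and 1.19 RPM (quartiles 1.12 and 1.45) for GRdim-only peaks. The differences of medians, 0.27 and 0.33 RPM, both gave p = 1e-05 in a two-sided permutation test over peaks, the smallest that 100000 resamples can give. A shared peak must pass the floor in both libraries. Where binding is similar in both, the floor alone gives differences in this direction, so the p-values are not read as a finding. With equal binding and Poisson counts, the share of autosomal WT peaks listed in both would rise from 59.1% under 1.3 RPM to 100% at 3 RPM or more. In GRdim it would rise from 69.1% to 100%. That model takes each listed height as the true binding. Peaks were listed only above the floor, so heights near it are biased upward and the modelled shares there are too high. With part of each height above the floor removed, the shares under 1.3 RPM would be 53.6% in WT and 64.7% in GRdim. The right amount is unknown, so no conclusion is drawn from these low peaks. At 2 to 3 RPM the same removal gives 97.7% in WT and 98.5% in GRdim, against 48.8% and 56.0% observed. The observed share of autosomal WT peaks also listed in GRdim went from 14.8% (exact interval 12.1 to 17.8) among peaks under 1.3 RPM to 48.8% (37.4 to 60.2) among those of 2 to 3 RPM. It was 35.0% (20.6 to 51.7) among the 40 WT peaks of 3 RPM or more. In the GRdim list the share went from 16.1% (12.7 to 19.997) under 1.3 RPM to 86.7% (59.5 to 98.3) among the 15 peaks of 3 RPM or more. Peak width could not be compared, since every listed peak was 200 bp wide.

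**Figure D1:**
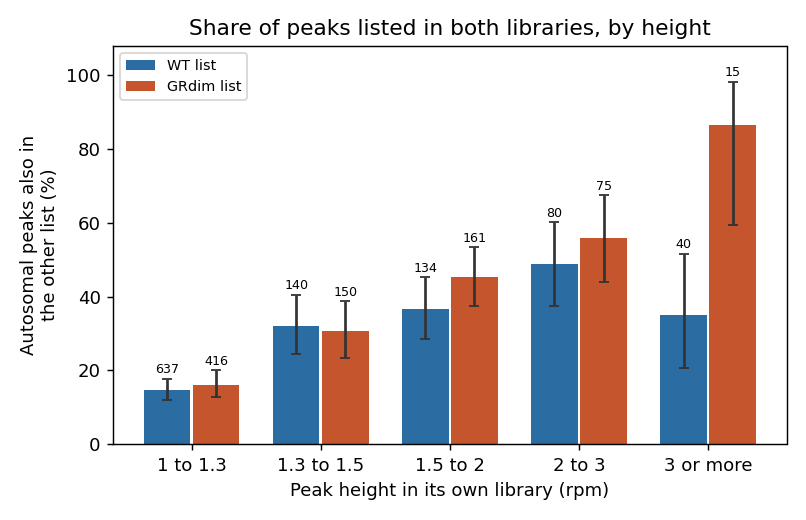
Share of autosomal peaks that are also in the other list (vertical axis, %), by peak height in RPM (horizontal axis), for the WT list (blue) and the GRdim list (orange); bars are shares, error bars 95% exact binomial intervals, and the number over each bar its peaks. The shares stand at 14.8% and 16.1% for the lowest peaks and at 35.0% and 86.7% for peaks of 3 RPM or more.

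The next question was how strongly the shared sites were occupied in each genotype. Heights at the 242 shared sites went together across peaks (Spearman's rho = 0.49, permutation p = 1e-05; Pearson's r on log values = 0.60, permutation p = 1e-05), although peaks are not independent replicates. The listed height was greater in GRdim at 145 sites and in WT at 97, of which 13 had equal reads in both libraries, with a median log2 ratio of GRdim over WT of 0.07 (SD 0.46 over sites). At the 50 sites with a summed height of 4 RPM or more the median log2 ratio was 0.014 (95% bootstrap interval -0.16 to 0.24). An exact binomial test of the reads at each site, adjusted by the Benjamini-Hochberg method over the 242 sites, separated the 2 libraries at 5 sites, 4 of them taller in WT (20 sites had an unadjusted p under 0.05). These sites are named because they passed that test, which was added after the heights had been seen. The widest gap was on chromosome 6 at 99125506 to 99125705, where 88 reads in WT stood against 20 in GRdim, 4.51 times the height (exact binomial adjusted p = 1.5e-09). WT was also taller on chromosome 13 at 5614123 to 5614322, by 3.36 times (72 against 22 reads, exact binomial adjusted p = 9.4e-06). The midpoints of that pair lay 111 bp apart, so its reads come from windows that overlap only in part. It would not count as shared with midpoints within 100 bp. On chromosome 17 at 26649569 to 26649768 the height in WT was 2.58 times that in GRdim, with 58 against 23 reads (exact binomial adjusted p = 0.0047). The chromosome 3 site at 146320445 to 146320644, with midpoints 77 bp apart, was 1.85 times as high in WT (117 against 65 reads, exact binomial adjusted p = 0.0046). The chromosome 5 site at 114395281 to 114395480 went the other way, with 72 reads in WT and 121 in GRdim, 1.64 times as high in GRdim (exact binomial adjusted p = 0.043). A site enters this comparison only if it passed the floor in both libraries, so the floor limits the ratios that low sites can show.

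**Figure D2:**
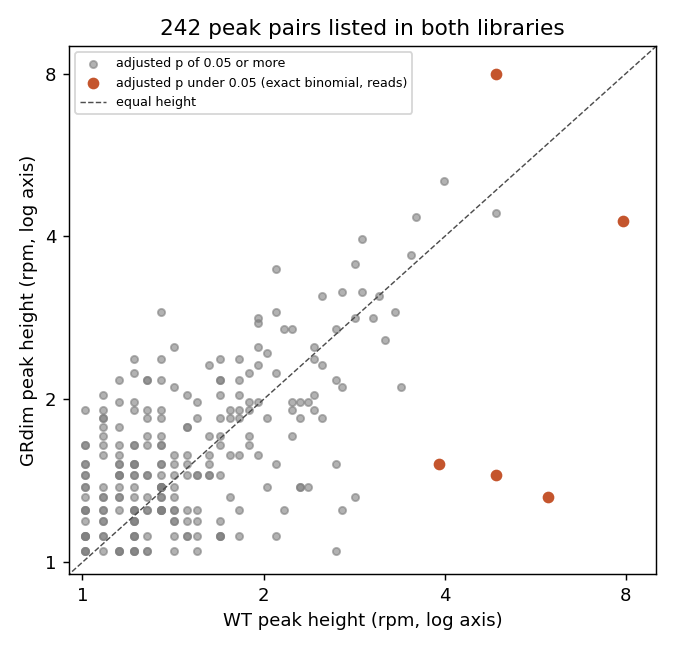
Height of each of the 242 shared peaks in the WT library (horizontal, RPM, log axis) against its height in the GRdim library (vertical, RPM, log axis); grey points have an adjusted p of 0.05 or more in the exact binomial test of reads, orange points are below it, and the dashed line marks equal height. Of the 5 orange points, 4 lie below the line (taller in WT) and 1 above it.

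The sites listed in WT alone were led by chromosome Y. The WT-only peaks with the greatest heights were on Y at 2883597 to 2883796 (15.48 RPM), 2780214 to 2780413 (12.10 RPM), 2782194 to 2782393 (10.27 RPM) and 1790516 to 1790715 (7.30 RPM), followed by a peak on chromosome 17 at 26672226 to 26672425 (7.10 RPM, 105 reads). That chromosome 17 peak lay 20.5 kb from the nearest GRdim peak. It was the tallest autosomal WT-only peak. The next autosomal ones, added to the naming rule after the Y peaks were seen, lay on chromosome 7 at 71041835 to 71042034 (6.42 RPM), chromosome 19 at 22022502 to 22022701 (6.22 RPM), chromosome 2 at 167579468 to 167579667 (5.07 RPM) and chromosome 11 at 68910489 to 68910688 (5.0 RPM). The nearest GRdim peak to the chromosome 11 site was 227 kb away.

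Sites listed in GRdim alone were lower at the top of the range. The tallest was on chromosome 9 at 99082703 to 99082902 (3.36 RPM, 51 reads). It was followed by chromosome 11 at 83460273 to 83460472 (3.30 RPM), chromosome 2 at 152614634 to 152614833 (2.97 RPM), chromosome 11 at 83479207 to 83479406 (2.83 RPM) and chromosome 2 at 28395587 to 28395786 (2.83 RPM). Among autosomal peaks of 1 list only, 26 of 790 in WT (3.29%, exact interval 2.16 to 4.79) and 2 of 576 in GRdim (0.347%, 0.042 to 1.249) reached 3 RPM (Fisher's exact test, two-sided, p = 5.7e-05, Benjamini-Hochberg adjusted over the 3 heights 0.00017). At a height of 2 RPM the same comparison gave 67 of 790 (8.48%, 6.63 to 10.6) and 35 of 576 (6.08%, 4.27 to 8.35), which did not differ by the test (Fisher's exact p = 0.097, adjusted 0.145). At 1.5 RPM the order turned, with 19.2% in WT and 21.4% in GRdim (Fisher's exact p = 0.34, adjusted 0.34). These heights were chosen after the lists had been seen, so the difference at 3 RPM is one of 3 looks at the same peaks.

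Peaks were then compared by chromosome. Chromosome Y carried 26 WT peaks and no GRdim peak. Of the 21 chromosomes tested, Y alone differed in its share of the lists after Benjamini-Hochberg adjustment (Fisher's exact adjusted p = 1.1e-05), and 4 had an unadjusted p under 0.05. The Y peaks lay between 1264182 and 2901805, had a median height of 1.89 RPM, and made up 5 of the 10 tallest peaks of the WT list. Chromosome X held 19 WT peaks and 5 GRdim peaks (Fisher's exact adjusted p = 0.20). Without chromosome Y, the shared fraction of WT peaks was 23.0%. The most peaks were on chromosomes 1 and 2 in WT (84 and 83) and on chromosomes 2 and 11 in GRdim (72 and 70).

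**Figure D3:**
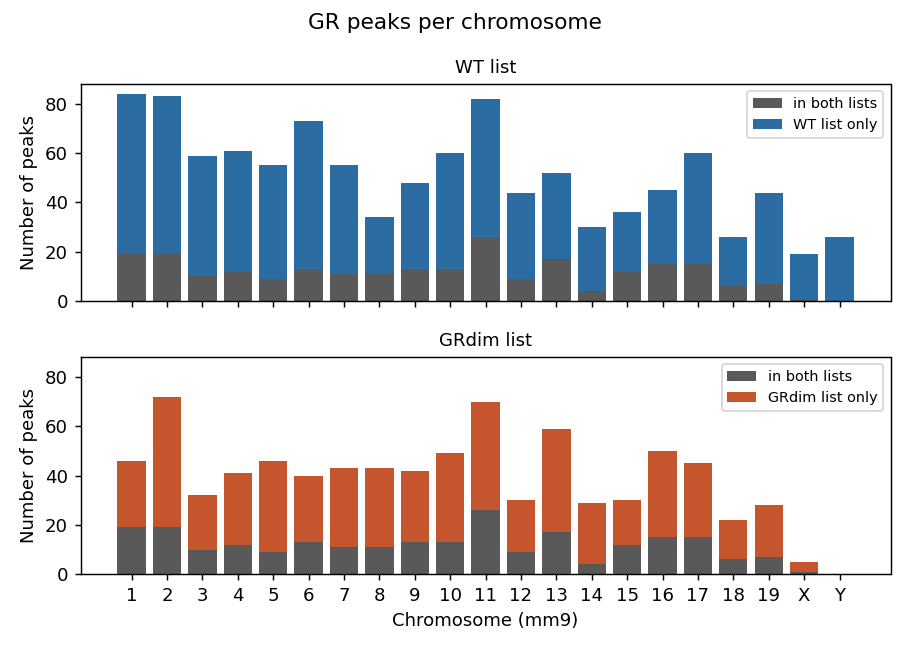
Number of GR peaks on each mm9 chromosome (horizontal axis) in the WT list (upper panel) and the GRdim list (lower panel); dark grey marks peaks in both lists and colour those in that list alone. Chromosome Y carries 26 peaks in WT and none in GRdim, and X carries 19 and 5.

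Some windows of 100 kb held several peaks of 1 library. In WT the densest were on Y, with 5 peaks at 1700001 to 1800000 and 4 at 2700001 to 2800000, and on chromosome 12 at 86800001 to 86900000, with 5 peaks of 1.08 to 4.33 RPM. Of those 5 on chromosome 12, 1 was shared with GRdim, where it was the only peak in the window and stood at 1.91 RPM. In GRdim, windows on chromosomes 12 and 11 tied for the most peaks. The window on chromosome 12 at 27100001 to 27200000 held 4 peaks of 1.52 to 2.57 RPM, with no WT peak within 924 kb of any of them. The others adjoined each other on chromosome 11: 83300001 to 83400000 also held 4 GRdim peaks of 1.12 to 1.85 RPM and no WT peak, and 83400001 to 83500000 held 3 GRdim peaks of 1.05 to 3.30 RPM and 1 WT peak of 1.35 RPM, which overlapped none of them. No test was made of these windows, which were picked for their counts.

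**Figure D4:**
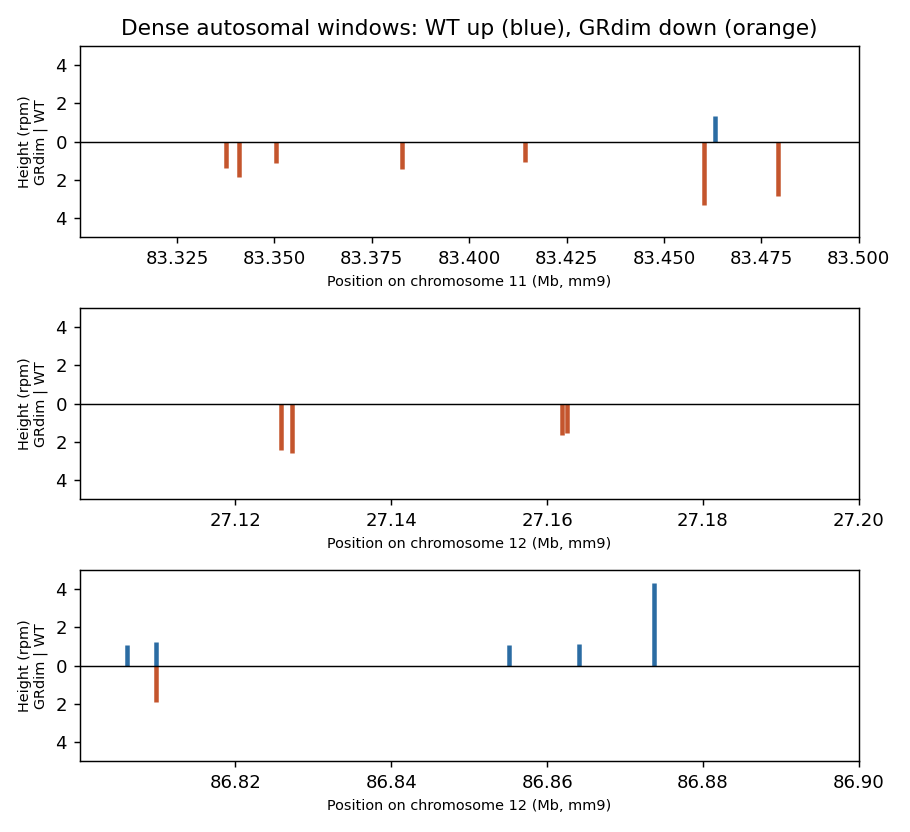
Positions of GR peaks in Mb on mm9 (horizontal axis) and their heights in RPM (vertical axis, WT upward in blue, GRdim downward in orange) in the densest autosomal windows of either list. The region on chromosome 11 holds 7 GRdim peaks and 1 WT peak, and the upper and lower chromosome 12 windows hold 4 GRdim peaks alone and 5 WT peaks with 1 GRdim peak.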

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

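The alternatives without chromosome Y, on autosomes alone or without the 2 tallest WT peaks among the shared pairs, and all those on tall peaks, on peaks in 1 list only and on near neighbours, were chosen after seeing the data. Of 44 alternative values, 34 stayed within the limits set for them, 8 moved, 1 was no longer past 0.05 and 1 reversed. Some of the 34 could not move, so the tally overstates stability. These were peak widths, GRdim values without chromosome Y (which has no GRdim peak) and the correlation over one-to-one pairs, which are all the pairs. None was run for the test of reads at shared sites or the comparison by chromosome. The share of autosomal peaks in 1 list only that reached a height, WT minus GRdim, was 2.94 percentage points at 3 RPM, 2.40 at 2 RPM and -2.11 at 1.5 RPM (Fisher's exact p = 5.7e-05, 0.097 and 0.34); the cause was not tested. Shared fractions held at 21.0% of WT and 27.5% of GRdim peaks with a 50% reciprocal overlap or midpoints within 100 bp, which are the same criterion for peaks of 1 width, and at 23.1% and 30.2% with edges within 500 bp. They were higher above the median height: keeping heights at or above the median of each list left 563 WT and 473 GRdim peaks, of which 33.0% and 41.6% met a peak of the other whole list. The 411 best-scored peaks of each list shared 28.7%, and lists cut to the same length of 822 peaks shared 27.0%, both above the 22.5% of the full WT list and below the 29.4% of the full GRdim list. The excess over random placement fell from 1754-fold on whole chromosomes to 128-fold within 50 kb and 21.3-fold within 5 kb, each with a permutation p of 0.001; the fold depends on how far a peak may move. The correlation of heights kept its direction and stayed past 0.05 under the alternatives run for it. Height differences between shared and other peaks were again 0.27 and 0.33 RPM without chromosome Y, but the floor alone can give their direction, so this says nothing of their stability. The part of tall autosomal peaks in 1 list only changed with the height asked for. It was 59.8% in WT and 49.0% in GRdim at 1.5 RPM, 55.8% and 38.9% at 2 RPM, and 65.0% and 13.3% at 3 RPM. The last GRdim value rests on 2 of 15 peaks. Distance to genes, annotation, motifs and gene lists were not run, nor their alternatives, for want of an mm9 reference. No library could be left out, since each genotype has 1. The floor of 15 or 16 reads limits what can be said of sites listed once: 60.8% of WT and 51.0% of GRdim peaks stood below 1.3 RPM.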

Other observations

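All tests in this part were chosen after the peak lists had been examined; the shared fractions by height, the tallest peaks and the numbers of near neighbours had been seen before these tests were written.

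Peaks of the 2 libraries also lay near each other without overlapping. Of the 580 GRdim-only peaks, 66 (11.4%, exact interval 8.91 to 14.2) lay within 20 kb of a WT peak, and 75 of the 834 WT-only peaks (8.99%, 7.14 to 11.1) lay within 20 kb of a GRdim peak. On chromosome 11 the GRdim-only peak at 83460273 to 83460472 stands 2.6 kb from a WT peak of 1.35 RPM. Random placement of the GRdim-only peaks within 500 kb of their position gave 23.9 ± 4.6 such peaks (SD over 1000 placements), so the observed number was 2.76 times as high (permutation p = 0.001, the smallest possible), which argues against random placement within a region; within 5 kb and 50 kb the excess was 4.11-fold and 2.15-fold. The near peak of the other list may itself be shared, and the counts were not split by this. The GRdim-only peak on chromosome 2 at 152614634 to 152614833, for example, lay 17.3 kb from a shared site. A candidate explanation is that both forms of the receptor use the same stretches of open chromatin, in part at different sites. Clustering of accessible sites on a scale below 500 kb would give the same excess with no link between the genotypes. Within each list, 191 of 1076 WT peaks and 100 of 822 GRdim peaks had a neighbour of their own list within 20 kb. The WT number includes peaks on chromosome Y, and neither number was compared with random placement. The lists hold no measure of accessibility to separate these explanations.

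Many tall autosomal peaks were listed in 1 library. Among autosomal WT peaks of 2 RPM or more, 53 of 120 were also in the GRdim list, while equal binding with Poisson noise and the floor would give 118, even after removal of 50% of each height above the floor. In the GRdim list 55 of 90 were shared, against 88.9 expected. Counting noise on equal binding is therefore too small to account for them. A lower enrichment of the GRdim library would not give the 35 GRdim-only autosomal peaks of 2 RPM or more (1.13 expected). A single factor was also tried as the whole cause of the WT-only peaks. It was set to leave even 20.7 of the 40 WT peaks of 3 RPM or more listed (14 were). Such a factor would leave 6.33 ± 2.38 (SD) of the 80 peaks of 2 to 3 RPM with the same removal. Without the removal it would leave 3.11 ± 1.70, where 39 were listed. Any single factor leaves a smaller share of the lower peaks, and the observed shares had been seen, so a misfit was foreseeable. These values give the size of the gap and are not an independent test of enrichment. A smaller loss of enrichment acting beside another cause, variation between ChIP libraries beyond counting noise, filters other than the floor and the genotype itself stay open, as no replicate library was analysed.

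The 26 WT peaks on chromosome Y, with none in GRdim, lie within 1.64 Mb, where no autosomal stretch of that length held more than 11 WT peaks. The height floor acting on equal coverage is excluded: the log10 probability that all 12 Y peaks of 2 RPM or more would fall below the floor was -306. A candidate explanation is that the WT cells had a Y chromosome and the GRdim cells did not, in which case the Y peaks would say nothing of the mutation. A higher share of peaks on X in GRdim was the outcome looked for under this explanation, written down after the lists had been examined. X held 0.608% of GRdim peaks (exact interval 0.198 to 1.41) and 1.81% of WT peaks outside Y (1.09 to 2.81, Fisher's exact p = 0.023, unadjusted). The share was lower in GRdim, the reverse of the outcome looked for. How the number of X peaks follows the copies of X was not measured, so this test cannot decide for or against the explanation. The sex of the mice cannot be told apart from other causes here, because X peaks are few, their binding may itself depend on genotype, and the sex of the input cells and the treatment of repeated Y sequence in the alignment are not given in the sources used here.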
